A study of Mus musculus with 36 samples.

How the data were processed

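RNA was sequenced from mouse forelimbs at stage E12.5. Distal and proximal forelimb tissue was dissected from individual pairs of limbs, per the labels' protocols, and poly(A) RNA was made into strand-specific TruSeq libraries read as single ends of 50 nucleotides on an Illumina HiSeq instrument. The 36 libraries fall into 12 groups of 3: wild type (WT) and 5 alleles that lack 1 or more CTCF binding sites (CBS) at the Hoxd cluster, each in 2 tissues. Groups and replicate numbers were taken from the sample titles. The labels give the strain as B6CBAF1 for every sample and name no litter, date or library batch. As each library comes from the limbs of an individual, p-values refer to the spread between embryos of a group.

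The authors deposited a table of whole-number read counts per Ensembl gene for all libraries, and a table of Cufflinks FPKM values (fragments scaled to gene length and library size) for the same libraries, per the file headers. The submitters' processing notes name cutadapt 1.16, STAR 2.7.0, Cufflinks 2.2.1, bedtools 2.27.1 and the mm10 genome build, without saying what each was used for. The counting settings, including whether strand was used, are not given in the sources used here, so reads of overlapping or antisense gene pairs may be shared between them. Gene coordinates are those of the deposited FPKM table on mm10. The count table holds 50833 genes, and 55052 genes are in that of FPKM values. All 4222 genes found only in the FPKM table lie on chromosome X (2618), Y (1568) or M (36), so the count-based results cover autosomes, and 3 genes of the count table are absent from the FPKM table. A column was matched to a sample by its title, and 0 columns were left without a sample. Total counts per library ran from 11062069 to 17727891. Pairs of replicates differed by more than sampling noise in every group (chi-square per degree of freedom 2.75 to 23.11), so all libraries were counted as separate replicates.

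Differences were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test (glmQLFit and glmQLFTest) after TMM scaling and filterByExpr on the groups. Mutants were compared with WT, and each allele with the preceding one of the series, in 1 fit of the 18 libraries of a tissue. The tissues were compared in the 6 WT libraries, and the difference between the tissues in the effect of an allele was tested as an interaction in 1 fit of all 36 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. For the HoxD genes the adjustment was also made over the list alone, and this count answers the comparison. Of the 9 HoxD genes listed, 8 were tested, because Hoxd1 lay under the count filter. Log2 fold changes are given with their standard error (SE), and levels as CPM (counts scaled to library size, by TMM over all 36 libraries) with the standard deviation (SD), with n = 3 in each group.

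Before the data were examined, the groups, the tests, the alternatives, 20 gene lists and a rule for the genes to be named were fixed. The lists were the HoxD cluster, HoxD flanks, other Hox clusters, distal limb patterning, proximal limb patterning, Hedgehog pathway, chondrogenesis, joint interzone, tendon and connective tissue, skeletal muscle, epidermis and ectoderm, endothelium, erythroid cells, macrophages and leukocytes, nerve and Schwann cells, proliferation, immediate early and heat shock, hypoxia and glycolysis, CTCF and cohesin, and sex linked genes. None of the 6 sex linked genes is in the count table, so that list was not tested. Each of the other lists was tested against all other genes with limma 3.58.1 camera at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with a correlation estimated from the data. Named are all tested HoxD genes and the HoxD flanks called over all genes. Outside these lists, up to 6 genes per direction and mutant (10 per direction between WT tissues) were named by the largest fold change among called genes with a mean of at least 50 counts in the higher group and no overlap between the libraries of both groups. Unnamed gene models were passed over in that step. Of a called list the up to 4 members with the smallest p were named. The exceptions are Rbm44 and the levels of Ihh, Gdf5 and Slc4a1 among the other observations, chosen after their values were seen, and 2 genes that the rules would name and that are not reported, for a reason unrelated to their values.

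The test was first tried on counts simulated from the means, dispersions and library sizes of each tissue. In them 200 genes with an average log2 CPM above 2 were changed. In the simulated comparison of Del(CBS1) with WT in distal tissue (15139 genes), 89.6% of 1.5-fold, 94% of 2-fold and 100% of 3-fold changes were recovered, and 12 of 201 calls (6%) were false. In proximal tissue (15562 genes) the shares were 76.1%, 95.5% and 98.5%, and 8 of 188 calls (4.3%) were false. The simulated libraries were independent, without structure shared among embryos or lines, so these shares may not hold for the real libraries or for lower genes.

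Whether replicate numbers pair libraries was checked on 10438 genes with a mean log2 CPM of at least 3, by correlating deviations from the group means. Across tissues, all 18 pairs of libraries with the same genotype and number correlated best with each other (r 0.24 to 0.71), and the sex read from sex linked FPKM values matched in 18 of 18. A number thus stands for an embryo, and the tissue and interaction comparisons are paired by design. Their values are nevertheless from fits without an embryo term, except where they are given as blocked. Across genotypes, 18 comparisons were checked, and in 2 of them, Del(CBS1-3) against WT in both tissues, every same-numbered pair had r above 0.1 (lowest r 0.12). Blocked counts over all genes are printed with the counts of these results where the counts differ. Blocked values are printed with the HoxD, flanking and other named genes, and with the lists between the WT tissues and in Del(CBS1-3), where they differ in call.

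Alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, only the 6 libraries compared, a replicate block, a fold change of at least 1.5 as well, each library left out in turn, limma on log2(FPKM + 0.1) with a minimum of 0.5 FPKM in at least 3 libraries, and fry for the lists. A further alternative, chosen after seeing the data, added as a covariate a score for tissue from across the dissection boundary. It was the mean log2 CPM of the skeletal muscle list in distal libraries, and of the distal limb patterning list without Hox genes in proximal libraries. The planned exclusion of X and Y genes had nothing to remove. Fold changes on the log2(FPKM + 0.1) scale understate the change of low genes. The median log2 fold change of all genes lay between -0.01 and 0.01 in every comparison.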

Results

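The transcriptome of the forelimb was measured by RNA-seq in mouse embryos at stage E12.5. The distal part of the forelimb holds the future digits, and the proximal part the arm. The wild type was compared with 5 alleles made by CRISPR/Cas9 in which sites bound by CTCF, a protein that shapes chromatin loops, were removed one after another at the Hoxd cluster: Del(CBS1), Del(CBS1-2), Del(CBS1-3), Del(CBS1-4) and Del(CBS1-5). Each genotype was represented by 3 libraries per tissue, 36 in all, with 11062069 to 17727891 counts each. The question of the design was how the loss of each further site altered the transcription of the Hoxd genes, which encode homeodomain proteins that pattern the limb along its length.

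The HoxD genes were read on chromosome 2 of mm10, in the order Hoxd13 (74668310 to 74671599), Hoxd12 (74675013 to 74677705), Hoxd11 (74682323 to 74684168), Hoxd10 (74691924 to 74695105), Hoxd9 (74697727 to 74700208), Hoxd8 (74704615 to 74707933), Hoxd4 (74721978 to 74729160) and Hoxd3 (74711927 to 74748271). The gene models of Hoxd3 and Hoxd4 overlap, so their counts are uncertain where reads could belong to either. Hoxd1 had 0 counts in the 3 distal WT libraries and 0.235 ± 0.0678 CPM (SD, n = 3) in proximal WT, and was too low to test.

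In WT, the genes at the Hoxd13 end were higher in distal tissue and those at the Hoxd3 end were higher in proximal tissue. Hoxd13 stood at 1020 ± 103 CPM in distal and 54.1 CPM in proximal tissue (log2 fold change 4.24 ± 0.34, SE), and Hoxd12 at 412 ± 20.9 and 70.2 CPM (2.55 ± 0.08). Hoxd3 (-3.13 ± 0.39), Hoxd8 (-2.48 ± 0.33), Hoxd4 (-2.15 ± 0.30), Hoxd9 (-1.48 ± 0.13) and Hoxd10 (-0.30 ± 0.06) were lower in distal tissue. In each of these 7 genes all 3 distal libraries lay on the same side of all 3 proximal ones (edgeR, Benjamini-Hochberg adjusted p over the list alone at most 0.00158), whereas Hoxd11 did not pass (0.00 ± 0.10). Evx2, the homeobox gene beside Hoxd13, was higher in distal tissue by 5.01 ± 0.63, and of the other flanking genes Lnpk (1.70), Chn1 (0.47), Atf2 (0.46) and Wipf1 (0.24) were higher as well. With embryos blocked Atp5g3 (0.19), Hnrnpa3 (0.21) and Nfe2l2 (-0.27) passed too (edgeR, Benjamini-Hochberg adjusted p = 0.017, 0.0167 and 0.0334).

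Beyond the cluster, 4578 of 14918 genes differed between the WT tissues in edgeR, 2024 higher and 2554 lower in distal tissue. With embryos blocked, the paired fit, 5763 were called, 2695 higher and 3068 lower. The highest by the naming rule were Evx1os (4.50), Hottip (4.29), Evx1 (3.99), Bhlha9 (3.75), Msx1 (3.65), Sost (2.99), Irx1 (2.99), Msx2 (2.89), Edar (2.75) and Sp8 (2.73), among them homeobox factors of the limb tip (Msx1, Msx2) and ectodermal regulators (Edar, Sp8). Evx1os and Hottip are antisense transcripts, whose reads cannot be told from those of a partner gene where strand was not used in counting. The lowest were genes of myogenic precursors and muscle fibres. Myoz2 had 0 counts in distal and 10.3 ± 0.548 CPM in proximal libraries, and Pax7, which marks muscle progenitors, stood at 0.0915 ± 0.104 and 19.8 ± 2.4 CPM. Myot (0.0439 and 8.76 CPM), Fgf6 (0.0231 and 4.18 CPM) and Trim54 (0.0228 and 4.02 CPM) were close to 0 in distal tissue, and Myh8 (-7.93), Lmod3 (-7.00), Cacna1s (-6.99), Tnnc2 (-6.92) and Acta1 (-6.87) completed the list.

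Of the gene lists, 14 separated the WT tissues by limma camera at the preset correlation, and 0 did so with an estimated correlation (lowest adjusted p = 0.0711, against 13 lists by fry). Skeletal muscle was lower in distal tissue, with 25 of 25 members down and a median of -5.77 (adjusted p = 0.0711 with an estimated correlation), including Myh3, Neb, Tnnc1 and Ttn. Distal limb patterning was higher, with 17 members up and 1 down adjusted over the list alone (16 and 1 over all genes; adjusted p = 0.207 with an estimated correlation), led by Wnt5a (1.46), Cyp26b1 (1.37), Lhx2 (2.18) and Aldh1a2 (2.39), genes of Wnt signalling (Wnt5a), retinoic acid turnover (Cyp26b1, Aldh1a2) and a LIM homeodomain factor (Lhx2). Proximal limb patterning was lower in 15 of 18 members adjusted over the list alone (14 over all genes; adjusted p = 0.125 with an estimated correlation), led by Pkdcc (-5.46), Emx2 (-1.48) and Tbx18 (-0.81). Chondrogenesis was lower (15 down and 3 up, with Cnmd at -3.12 and Runx3 at -3.68; adjusted p = 0.234 with an estimated correlation). Tendon and connective tissue was lower as well (12 down and 1 up, with Lum at -5.03 and Dcn at -3.71; adjusted p = 0.0802 with an estimated correlation). Endothelium (9 of 14 down) and nerve and Schwann cells (9 of 11 down) were lower too, with adjusted p = 0.234 and 0.0711 with an estimated correlation. The Hedgehog pathway (6 down and 1 up) and joint interzone (6 down and 1 up adjusted over the list alone, 6 down over all genes) were called lower, with adjusted p = 0.327 and 0.357 with an estimated correlation. When embryos were blocked, joint interzone lost its call (camera adjusted p = 0.0702, median -0.78), and macrophages and leukocytes were called lower (block adjusted p = 0.0372, median -0.37). All 16 proliferation genes, among them Top2a (0.62) and Mki67 (0.52), were higher in distal tissue (adjusted p = 0.207 with an estimated correlation). Epidermis and ectoderm (13 up and 3 down of 20 adjusted over the list alone, 12 and 3 over all genes) and erythroid cells (Hbb-y alone of 11) were called higher, each with adjusted p = 0.357 with an estimated correlation. So were CTCF and cohesin (6 of 9) and HoxD flanks (5 of 12), with adjusted p = 0.262 and 0.125 with an estimated correlation.

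Removal of the first site left the distal HoxD genes without a call. Hoxd10 (97 ± 2.47 against 111 ± 5.91 CPM in WT, -0.20 ± 0.07) and Hoxd13 (-0.21 ± 0.08) had edgeR Benjamini-Hochberg adjusted p = 0.0591 over the list alone, with 3 and 2 of 3 Del(CBS1) libraries below all WT libraries. Hoxd3 (-0.76 ± 0.63), Hoxd4 (-1.01 ± 0.43), Hoxd8 (-0.45 ± 0.41), Hoxd9 (-0.36 ± 0.20), Hoxd11 (-0.09 ± 0.11) and Hoxd12 (0.02 ± 0.09) did not pass either. Over all genes edgeR called 0 HoxD genes, with 0 also over the list alone, where DESeq2 called 2 and limma on FPKM 0, and leaving out single libraries gave 0 to 3. Outside the cluster 1 gene rose and 4 fell. Fignl1, which acts in homologous recombination, rose by 0.55 ± 0.09. The chromatin protein gene Hmgb2 (-2.10 ± 0.26, 11.8 ± 1.15 against 50.4 ± 15.7 CPM), Tmco1 of the endoplasmic reticulum (-0.46 ± 0.08), the alpha-globin gene Hba-a1 (-0.92 ± 0.15) and 1 unnamed gene model, Gm10350, fell. Hba-a1 can share reads with its near-identical copy Hba-a2 (2.37 ± 1.07, which did not pass), so its value is uncertain.

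In all, 5 of 15361 genes passed in this comparison, against 1488 at an unadjusted p under 0.05, 65 calls by DESeq2 and 1 by limma on FPKM. Leaving out WT 3 raised the count to 40 and leaving out WT 1 to 8, while it was 2, 1 and 2 without Del(CBS1) 1, 2 and 3. Limma camera called the HoxD list lower (median -0.29, adjusted p = 0.479 with an estimated correlation). Erythroid cells were called lower as well (Hba-a1 and Hbb-bt, 2 of 12 members, down adjusted over the list alone, 1 over all genes; adjusted p = 0.59 with an estimated correlation). With 0 members passing, CTCF and cohesin was called lower, and epidermis and ectoderm and macrophages and leukocytes higher (adjusted p = 0.485, 0.479 and 0.491 with an estimated correlation).

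In proximal tissue the same allele had lower counts of the genes at the Hoxd3 end. Hoxd3 fell from 8.81 to 4.32 CPM (-1.04 ± 0.26), Hoxd4 from 22.1 ± 1.95 to 12.9 ± 0.735 CPM (-0.77 ± 0.19) and Hoxd8 from 36.1 to 24.8 CPM (-0.54 ± 0.11). In each, all 3 Del(CBS1) libraries lay below all 3 WT libraries (edgeR, Benjamini-Hochberg adjusted p over the list alone = 0.0019, 0.0019 and 0.000537). Over all genes tested 0 HoxD genes passed, with Hoxd8 nearest at 0.0883. Hoxd9 (-0.15 ± 0.09), Hoxd10 (-0.04 ± 0.08), Hoxd11 (0.04 ± 0.11), Hoxd12 (0.04 ± 0.16) and Hoxd13 (0.15 ± 0.41) did not pass.

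Among 15813 genes, 7 changed in proximal Del(CBS1) tissue, 3 up and 4 down, against 1123 at an unadjusted p under 0.05, 25 by DESeq2 and 6 by limma on FPKM. The collagen VI gene Col6a5 rose by 1.79 ± 0.26 (31.9 ± 2.26 against 9.29 ± 3.88 CPM) and the phosphatase gene Ppm1m by 0.51 ± 0.09, together with the germ cell RNA-binding gene Rbm44. Tmco1 (-0.55 ± 0.05), the microtubule-associated protein gene Map2 (-0.35 ± 0.06), Hba-a1 (-0.77 ± 0.13, uncertain because of Hba-a2) and the pseudogene Bod1-ps fell. The count was 12 without WT 1, 15 without WT 3, 1 without Del(CBS1) 2 and 4 without Del(CBS1) 3. The HoxD list was the 1 list called by camera (median -0.10, adjusted p = 0.276 with an estimated correlation).

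With 2 sites removed, all 8 tested HoxD genes fell in distal tissue. Hoxd10 went from 111 ± 5.91 to 52 ± 4.54 CPM (-1.12 ± 0.07; edgeR, Benjamini-Hochberg adjusted p over the list alone = 3.68e-11), and Hoxd9 from 24.2 ± 4.8 to 9.01 ± 2.03 CPM (-1.45 ± 0.21). Hoxd11 (-0.71 ± 0.11), Hoxd12 (-0.35 ± 0.09), Hoxd13 (-0.30 ± 0.08), Hoxd4 (-1.93 ± 0.45) and Hoxd3 (-2.52 ± 0.76) fell as well, each with 3 of 3 mutant libraries below all WT libraries. Hoxd8 fell from 6.45 to 3.3 CPM with 1 of 3 libraries below all WT libraries (edgeR, Benjamini-Hochberg adjusted p = 0.0294 over the list alone and 0.137 over all genes), so that 7 of the 8 passed over all genes. Of the flanking genes, Lnpk (-0.39 ± 0.12), Atf2 (-0.20 ± 0.05) and Hnrnpa3 (-0.29 ± 0.06) fell.

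Outside the cluster this comparison had more calls than any other with WT. In edgeR 686 genes rose and 920 fell, 1606 of 15361, against 4085 at an unadjusted p under 0.05, and 311 of the calls exceeded 1.5-fold. In this and the other comparisons with WT the allele was not separated from other differences between the line and the WT embryos. All 3 Del(CBS1-2) embryos were female, against 2 of 3 in WT. Their distal skeletal muscle score (mean log2 CPM) was 1.93 to 2.63, against 0.98 to 1.18 in WT. Genes that rose most were Chdh (2.30 ± 0.67), an enzyme of choline metabolism, Rbm46 (2.10 ± 0.39), a germ cell RNA-binding protein, the transcription factor genes Foxf2 (2.02 ± 0.53), Irx6 (1.85 ± 0.48) and Runx3 (1.77 ± 0.38), and Cytl1 (1.75 ± 0.45), a secreted protein of cartilage. The genes that fell most were processed copies of other genes. Rps18-ps6 went from 96.5 ± 40.8 to 0.146 ± 0.0234 CPM, Pcna-ps2 from 37.3 ± 13.5 to 0.479 ± 0.139, Hmga1b from 31.6 ± 12.8 to 0.389 ± 0.159, Rnps1-ps from 18.4 to 0.119, Glo1-ps from 7.9 to 0.066 and Rps15a-ps8 from 3.81 ± 3.26 to 0 CPM. Rps15a-ps8 had 79, 86 and 1 counts in the distal WT libraries, so its level differed among WT embryos too. Reads of 50 nucleotides can be shared between such copies and their near-identical parent genes, which was not checked against sequence, so the values are uncertain.

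Gene lists of the skeleton and muscle were higher in distal Del(CBS1-2) tissue. Chondrogenesis had 14 of 22 members up and 1 down adjusted over the list alone (9 up over all genes), led by Runx3, Col10a1 (0.83 ± 0.21), Col2a1 (0.59 ± 0.15) and Cytl1. Its camera call gave an adjusted p = 0.273 with an estimated correlation. The Hedgehog pathway had 10 of 11 up adjusted over the list alone and 6 over all genes, with Ihh (1.36 ± 0.39), Gas1 (0.70 ± 0.17) and Smo (0.17 ± 0.04) among them (adjusted p = 0.19 with an estimated correlation). Joint interzone (7 of 11 up adjusted over the list alone and 3 over all genes; Gdf5 0.85, Gdf6 0.65; adjusted p = 0.273 with an estimated correlation) and tendon and connective tissue (6 of 15 and 2; Postn 1.46, Col5a1 0.42; adjusted p = 0.306 with an estimated correlation) were called higher. Skeletal muscle, which was higher in proximal than in distal WT tissue, was also called higher here, with 12 of 24 up adjusted over the list alone and 2 over all genes (adjusted p = 0.306 with an estimated correlation). Myod1 rose by 1.27, and Pax7 stood at 1.05 against 0.0915 CPM. Proximal limb patterning was called higher (3 of 18 up on both counts; adjusted p = 0.286 with an estimated correlation) through Tbx18 (0.22), Pbx3 (0.37) and Tbx5 (0.27). CTCF and cohesin genes were lower (5 of 9 adjusted over the list alone and 4 over all genes), among them Pds5b (-0.24 ± 0.05), Nipbl (-0.20 ± 0.04), Wapl (-0.20 ± 0.05) and Pds5a (-0.16 ± 0.04), with an adjusted p = 0.273 with an estimated correlation. Erythroid genes were lower, with 5 of 12 down and 1 up adjusted over the list alone and 2 down over all genes (Klf1 -1.36 ± 0.38; adjusted p = 0.428 with an estimated correlation). The HoxD list kept its call (median -1.06, adjusted p = 0.0237 with an estimated correlation). With the boundary score as a covariate 196 genes were called, limma on FPKM called 869, and the count was 979 without WT 2 and 756, 607 and 776 without Del(CBS1-2) 1, 2 and 3.

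In proximal Del(CBS1-2) tissue 7 of 8 HoxD genes fell, adjusted over the list alone, and 5 over all genes. Hoxd9 went from 67.2 to 41.1 CPM (-0.71 ± 0.09; edgeR, Benjamini-Hochberg adjusted p over the list alone = 3.07e-06), Hoxd8 from 36.1 to 21.1 CPM (-0.78 ± 0.11) and Hoxd10 from 136 to 93.2 CPM (-0.55 ± 0.08). Hoxd4 (-1.24 ± 0.19), Hoxd3 (-1.40 ± 0.26), Hoxd12 (-0.64 ± 0.17) and Hoxd11 (-0.34 ± 0.11) fell too, and each of the 7 had all 3 mutant libraries below all WT libraries. Hoxd13 (-0.66 ± 0.42) did not pass. Among all 15813 genes 40 rose and 74 fell, 114 in sum, against 3084 at an unadjusted p under 0.05. Smpd3, a neutral sphingomyelinase active in cartilage and bone (chromosome 8, 106252548 to 106337988), rose from 1.5 ± 0.703 to 10.6 ± 0.91 CPM (2.79 ± 0.47). Other increases were in Tdrd1 (1.23 ± 0.23), a germ line protein, Pappa2 (1.17 ± 0.21), a protease acting on IGF-binding proteins, and Emx2os (1.15 ± 0.18), which is antisense to Emx2 and uncertain without strand. The sphingomyelin synthase gene Sgms2 (1.05 ± 0.22) and the imprinted gene Phlda2 (1.04 ± 0.23) rose too. The copies Rps18-ps6 (92.3 to 0.0921 CPM), Hmga1b (24.2 to 0.223), Pcna-ps2 (24.1 to 0.226), Rnps1-ps (16.3 to 0.233), Glo1-ps (6.89 to 0.0854) and Atp6v0c-ps2 (5.87 to 0.0242) fell, with the same uncertainty.

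The lists of this tissue moved at the preset correlation, and the HoxD list alone kept its call with an estimated one (median -0.69, adjusted p = 0.00549). Proliferation was lower, with 15 of 16 members down adjusted over the list alone and 1, the checkpoint kinase gene Bub1 (-0.55 ± 0.09), over all genes (adjusted p = 0.339 with an estimated correlation). Chondrogenesis was higher in 17 of 22 members and lower in 3 adjusted over the list alone, and in 0 over all genes in edgeR (adjusted p = 0.339 with an estimated correlation). Comp (2.12 ± 0.60), Cnmd (0.98 ± 0.27) and Matn4 (0.50 ± 0.14), genes of cartilage matrix, rose adjusted over the list alone, whereas Sox9, the early regulator of cartilage, fell by 0.41. Tendon and connective tissue (10 up and 1 down), skeletal muscle (10 up and 1 down) and endothelium (4 up) were called higher, each with adjusted p = 0.339 with an estimated correlation. So were epidermis and ectoderm (4 up and 1 down), macrophages and leukocytes (2 up) and joint interzone (1 up), each with adjusted p = 0.365 with an estimated correlation. Distal limb patterning (3 down) and CTCF and cohesin (2 down) were called lower, with adjusted p = 0.418 and 0.339 with an estimated correlation. These counts are adjusted over each list alone, and over all genes edgeR called 0 members. The edgeR count of 114 was 64 with a replicate block, 520 by DESeq2 and 40 by limma on FPKM, and it was 49 without WT 1, 291 without WT 2 and 30, 41 and 31 without Del(CBS1-2) 1, 2 and 3.

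Del(CBS1-3) had distal HoxD levels near those of Del(CBS1-2). Hoxd10 stood at 54.3 ± 4.14 CPM (-1.05 ± 0.07 against WT; edgeR, Benjamini-Hochberg adjusted p over the list alone = 1.23e-10) and was the 1 gene of 15361 called over all genes. Adjusted over the list alone, Hoxd9 (-1.25 ± 0.21), Hoxd11 (-0.59 ± 0.11), Hoxd12 (-0.37 ± 0.09), Hoxd13 (-0.26 ± 0.08), Hoxd4 (-1.55 ± 0.45) and Hoxd3 (-1.70 ± 0.71) fell too, 7 of 8 in all. Of the mutant libraries 2 of 3 lay below all WT libraries in Hoxd13 and Hoxd3 and 3 of 3 in the others. Hoxd8 (-0.71 ± 0.42) did not pass. The HoxD list was the 1 list called by camera (median -0.88, adjusted p = 0.0064 with an estimated correlation), and with a replicate block epidermis and ectoderm was called as a second list (adjusted p = 0.0486, median 0.16). At an unadjusted p under 0.05 there were 2135 genes, DESeq2 called 136 and limma on FPKM 1. The count rose from 1 to 169 without WT 1 and 118 without WT 3, and was 3 without WT 2, Del(CBS1-3) 2 or Del(CBS1-3) 3.

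In proximal Del(CBS1-3) tissue 7 of 8 HoxD genes fell adjusted over the list alone and 3 over all genes. Hoxd3 went from 8.81 to 2.42 CPM (-1.86 ± 0.27; edgeR, Benjamini-Hochberg adjusted p over the list alone = 1.52e-05, 3 of 3 libraries below all WT libraries), Hoxd4 from 22.1 ± 1.95 to 9.72 ± 3.59 CPM (-1.19 ± 0.19) and Hoxd8 from 36.1 to 23.5 CPM (-0.63 ± 0.11). Hoxd9 (-0.34 ± 0.09), Hoxd10 (-0.40 ± 0.08), Hoxd12 (-0.76 ± 0.17) and Hoxd13 (-1.44 ± 0.44) fell over the list alone, and Hoxd11 (-0.11 ± 0.11) did not pass. Hoxd13 was uneven among the proximal WT libraries, with 490, 1443 and 498 counts, and WT 2 also had the highest mean log2 CPM of distal limb patterning genes without Hox genes among the 18 proximal libraries (5.82). Without WT 2 the log2 fold change of Hoxd13 was -0.84 and did not pass. Outside the cluster Cox8a (0.33 ± 0.06), of the respiratory chain, and the ferritin gene Fth1 (0.26 ± 0.05) rose. The DNA dioxygenase gene Tet2 (-0.39 ± 0.07), the osmotic stress factor Nfat5 (-0.38 ± 0.07), Ubn2 (-0.27 ± 0.05) and Arhgap32 (-0.27 ± 0.05) fell, with 2 unnamed models among the 11 calls. With a replicate block 13 genes were called, and edgeR Benjamini-Hochberg adjusted p rose to 0.0777 for Fth1 and 0.0504 for Arhgap32, whose libraries did not overlap in 3 of 3 against 3.

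At an unadjusted p under 0.05 this comparison had 2066 of 15813 genes, DESeq2 called 144, limma on FPKM 6 and the boundary score as a covariate left 0. The count was 52 without WT 1, 1 without WT 2 or WT 3, and 0 without Del(CBS1-3) 2 or 3. Camera called the HoxD list lower (median -0.69, adjusted p = 0.00456 with an estimated correlation). Distal limb patterning was lower (2 of 23 down adjusted over the list alone, Sall1 -0.72 ± 0.18 and Hoxa13 -1.58 ± 0.47; adjusted p = 0.564 with an estimated correlation). So was the Hedgehog pathway (0 of 11 by edgeR; adjusted p = 0.243 with an estimated correlation). Skeletal muscle was higher (2 of 25 up adjusted over the list alone, Myog 0.38 ± 0.11 and Myod1 0.45 ± 0.13; adjusted p = 0.563 with an estimated correlation). Proximal limb patterning (0 of 18) and erythroid cells (0 of 12) were called higher, with adjusted p = 0.548 and 0.563 with an estimated correlation. None of these members passed over all genes.

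The 4-site deletion had the lowest distal level of Hoxd9, Hoxd11 and Hoxd12 of the series. Hoxd9 stood at 7.24 ± 0.518 CPM against 24.2 ± 4.8 in WT (-1.74 ± 0.22), Hoxd11 at 34.9 against 67.5 (-0.96 ± 0.11) and Hoxd12 at 266 against 412 ± 20.9 (-0.63 ± 0.09). Hoxd10 stood at 54.1 ± 2.34 against 111 ± 5.91 (-1.04 ± 0.07; edgeR, Benjamini-Hochberg adjusted p over the list alone = 1.25e-10). These 4 passed over all genes, and adjusted over the list alone Hoxd13 (-0.28 ± 0.08), Hoxd8 (-1.21 ± 0.43), Hoxd4 (-1.84 ± 0.46) and Hoxd3 (-2.36 ± 0.76) fell as well, 8 of 8. In Hoxd8 1 of 3 mutant libraries lay below all WT libraries, and in the others 3 of 3. Beyond the cluster 5 genes rose: Rprm (1.18 ± 0.19), a p53 target that arrests the cell cycle, Ccn2 (1.01 ± 0.16), a matricellular protein of connective tissue, the tetraspanin gene Cd9 (0.78 ± 0.14), Cdk5rap1 (0.68 ± 0.09) and the heparan sulphate enzyme gene Hs6st1 (0.42 ± 0.07). The fatty acid desaturase gene Scd1 (-0.52 ± 0.07), the polyamine enzyme gene Odc1 (-0.41 ± 0.07) and the RNA regulators Rc3h1 (-0.29 ± 0.05) and Tut4 (-0.27 ± 0.04) fell.

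Together with the 4 HoxD genes these made 13 calls of 15361, against 2347 genes at an unadjusted p under 0.05, 295 by DESeq2 and 12 by limma on FPKM. The count was 525 without WT 2 and 113 without Del(CBS1-4) 2, and 7, 7, 7 and 6 without WT 1, WT 3, Del(CBS1-4) 1 and Del(CBS1-4) 3. Camera called the HoxD list lower, with or without an estimated correlation (median -1.13, adjusted p = 0.00208 with it). Chondrogenesis was higher in 15 of 22 members adjusted over the list alone, among them Cytl1 (1.88 ± 0.45), Matn3 (1.31 ± 0.30), Col10a1 (1.02 ± 0.21) and Col11a1 (0.80 ± 0.19), with adjusted p = 0.145 with an estimated correlation. Tendon and connective tissue (10 of 15, with Dcn 0.98 and Col1a1 0.68) and joint interzone (8 of 11, with Gdf5 0.79 and Gdf6 0.54) were higher by the same count, with adjusted p = 0.158 with an estimated correlation. The Hedgehog pathway was higher (8 of 11, with Ihh 1.35 and Hhip 1.34; adjusted p = 0.116 with an estimated correlation). So was epidermis and ectoderm (5 up and 1 down of 20, with Wnt7a 0.53 and Fgf8 -0.74; adjusted p = 0.22 with an estimated correlation). Skeletal muscle was called higher with 0 of 24 members passing in edgeR (median 0.96, adjusted p = 0.457 with an estimated correlation). Erythroid cells were lower in 7 of 12 members adjusted over the list alone (Epb42 -1.48 ± 0.33, Slc4a1 -1.11 ± 0.25; adjusted p = 0.22 with an estimated correlation). HoxD flanks were lower in 3 of 14 members, with 1 up (Chn1 -0.24 ± 0.05, Atf2 -0.18 ± 0.05; adjusted p = 0.145 with an estimated correlation). Over all genes 0 members of these lists other than HoxD passed in edgeR.

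In proximal Del(CBS1-4) tissue 6 of 8 HoxD genes fell adjusted over the list alone. Hoxd4 went from 22.1 ± 1.95 to 10 ± 0.361 CPM (-1.14 ± 0.19; edgeR, Benjamini-Hochberg adjusted p = 8.74e-05, 3 of 3 libraries below all WT libraries). The others were Hoxd3 (-1.35 ± 0.26), Hoxd8 (-0.59 ± 0.11), Hoxd9 (-0.46 ± 0.09), Hoxd12 (-0.56 ± 0.17) and Hoxd11 (-0.26 ± 0.11). Hoxd10 (-0.10 ± 0.08) and Hoxd13 (-0.02 ± 0.41) did not pass. Over all 15813 genes edgeR called 0, with Hoxd4 lowest at adjusted p = 0.0888, against 2229 genes at an unadjusted p under 0.05, 97 calls by DESeq2 and 0 by limma on FPKM. Without WT 2 the count was 293, without Del(CBS1-4) 2 it was 10 and without Del(CBS1-4) 1 it was 1. Camera called the HoxD list lower (median -0.51, adjusted p = 0.0208 with an estimated correlation). Proliferation genes were lower in 13 of 16 members adjusted over the list alone, among them Pcna (-0.39 ± 0.12) and the replication helicase gene Mcm7 (-0.32 ± 0.10), with adjusted p = 0.354 with an estimated correlation. Pcna can share reads with its copy Pcna-ps2, so its value is uncertain. Chondrogenesis (11 up and 1 down of 22, with Comp 2.07, Matn1 1.18 and Sox9 -0.48) and tendon and connective tissue (6 up and 1 down of 15, with Thbs2 1.07) were called higher. Proximal limb patterning was called lower (1 down, Shox2 -0.43, and 1 up, Irx5 0.47). These 3 lists had adjusted p = 0.53 with an estimated correlation. Skeletal muscle and epidermis and ectoderm were called higher with 0 members passing (adjusted p = 0.722 with an estimated correlation for both). All counts of members are adjusted over the list alone.

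With 5 sites removed, distal HoxD levels lay nearer to WT. Hoxd10 stood at 85.6 ± 5.13 CPM against 111 ± 5.91 (-0.39 ± 0.07; edgeR, Benjamini-Hochberg adjusted p over the list alone = 0.000168, 3 of 3 libraries below all WT libraries), and it was the 1 HoxD gene called over all genes (0.0323). Hoxd12 (349 against 412 ± 20.9 CPM, -0.25 ± 0.09) and Hoxd4 (1.91 against 4.96 CPM, -1.38 ± 0.44) fell adjusted over the list alone, 3 of 8 in all. Hoxd9 (-0.41 ± 0.20), Hoxd11 (-0.22 ± 0.11), Hoxd13 (-0.11 ± 0.08), Hoxd8 (0.02 ± 0.40) and Hoxd3 (-1.33 ± 0.67) did not pass. The HoxD count was 1 without WT 1, 6 without WT 2 and 1 without Del(CBS1-5) 3, and 1 by limma on FPKM. Elsewhere Fignl1 rose by 0.55 ± 0.09, and Zbtb20 (-0.79 ± 0.14), a zinc finger factor, Pced1a (-0.60 ± 0.09) and the transcript AA465934 (-2.78 ± 0.41) fell, as did the copy Pcna-ps2 (37.3 ± 13.5 to 0.609 ± 0.21 CPM, uncertain because of the parent Pcna).

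This comparison had 10 calls of 15361, 1 up and 9 down, against 2008 genes at an unadjusted p under 0.05, 119 by DESeq2 and 4 by limma on FPKM. The count was 320 without WT 3, 114 without Del(CBS1-5) 3, 6 without WT 1, 3 without WT 2 and 3 and 2 without Del(CBS1-5) 1 and 2. By camera the HoxD list was lower (median -0.32, adjusted p = 0.232 with an estimated correlation). Proliferation was higher in 6 of 16 members adjusted over the list alone, led by Pcna (0.53 ± 0.11), Plk1 (0.19 ± 0.06), Cdc20 (0.18 ± 0.06) and Aurkb (0.17 ± 0.05), with adjusted p = 0.592 with an estimated correlation, and Pcna can share reads with Pcna-ps2. Joint interzone was called lower with 2 of 11 members down adjusted over the list alone, Chrd (-0.53) and Barx1 (-1.99). Erythroid cells were called higher, and chondrogenesis, Hedgehog pathway, tendon and connective tissue and skeletal muscle lower, with 0 members passing over the list alone. Skeletal muscle had adjusted p = 0.695 with an estimated correlation and the other 5 of these lists 0.592. Over all genes 0 members of any of them passed in edgeR.

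In proximal Del(CBS1-5) tissue the 4 genes at the Hoxd3 end fell. Hoxd4 went from 22.1 ± 1.95 to 9.84 ± 1.38 CPM (-1.15 ± 0.19), Hoxd8 from 36.1 to 23.3 CPM (-0.63 ± 0.11), Hoxd9 from 67.2 to 45.9 CPM (-0.55 ± 0.09) and Hoxd3 from 8.81 to 3.33 CPM (-1.40 ± 0.26). Each had 3 of 3 libraries below all WT libraries (edgeR, Benjamini-Hochberg adjusted p over the list alone = 3.46e-05 for the first 3 and 8.6e-05 for Hoxd3). Hoxd4, Hoxd8 and Hoxd9 also passed over all genes (0.0205), and Hoxd3 did not (0.0556). Hoxd10 (-0.11 ± 0.08), Hoxd11 (0.07 ± 0.11), Hoxd12 (-0.03 ± 0.16) and Hoxd13 (-0.28 ± 0.41) did not pass. Mns1 (0.72 ± 0.11), a protein of motile cilia, Fignl1 (0.56 ± 0.10) and the RNA polymerase I subunit gene Polr1b (0.47 ± 0.08) rose. The receptor gene Sirpa (-0.46 ± 0.08), AA465934 (-2.35 ± 0.39) and Pcna-ps2 (24.1 ± 8.43 to 0.311 ± 0.209 CPM, with the same uncertainty) fell.

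There were 11 calls of 15813 in this comparison, 4 up and 7 down, against 1025 at an unadjusted p under 0.05, 32 by DESeq2 and 3 by limma on FPKM. The count was 47 without WT 3, 3 and 4 without WT 1 and 2, and 2, 2 and 6 without Del(CBS1-5) 1, 2 and 3. Camera called the HoxD list lower (median -0.41, adjusted p = 0.0287 with an estimated correlation) and erythroid cells higher (median 0.78, adjusted p = 0.0334 with an estimated correlation), with 8 of 12 members up and 1 down adjusted over the list alone and 0 over all genes in edgeR. The globin genes Hbb-bt (0.91 ± 0.27), Hba-x (0.89 ± 0.27) and Hbb-y (0.49 ± 0.13) and the red cell anion exchanger gene Slc4a1 (0.70 ± 0.20) rose. Joint interzone was lower in 6 of 11 members adjusted over the list alone (Nog -0.54, Wnt4 -0.36; adjusted p = 0.104 with an estimated correlation), and proliferation was higher in 1 of 16, Pcna (0.49 ± 0.12; adjusted p = 0.45 with an estimated correlation). Its value is uncertain, as the copy Pcna-ps2 held 29.8%, 28.6% and 13.8% of the summed counts of copy and parent in the proximal WT libraries and 0.0627% to 0.466% in proximal Del(CBS1-5). With 0 members passing in edgeR over the list alone or over all genes, proximal limb patterning was called higher (adjusted p = 0.367 with an estimated correlation) and hypoxia and glycolysis lower (median -0.18, adjusted p = 0.111 with an estimated correlation). Called lower in the same way were chondrogenesis, tendon and connective tissue and endothelium (adjusted p = 0.45 with an estimated correlation), macrophages and leukocytes (0.503) and skeletal muscle (0.578).

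**Figure D1:**
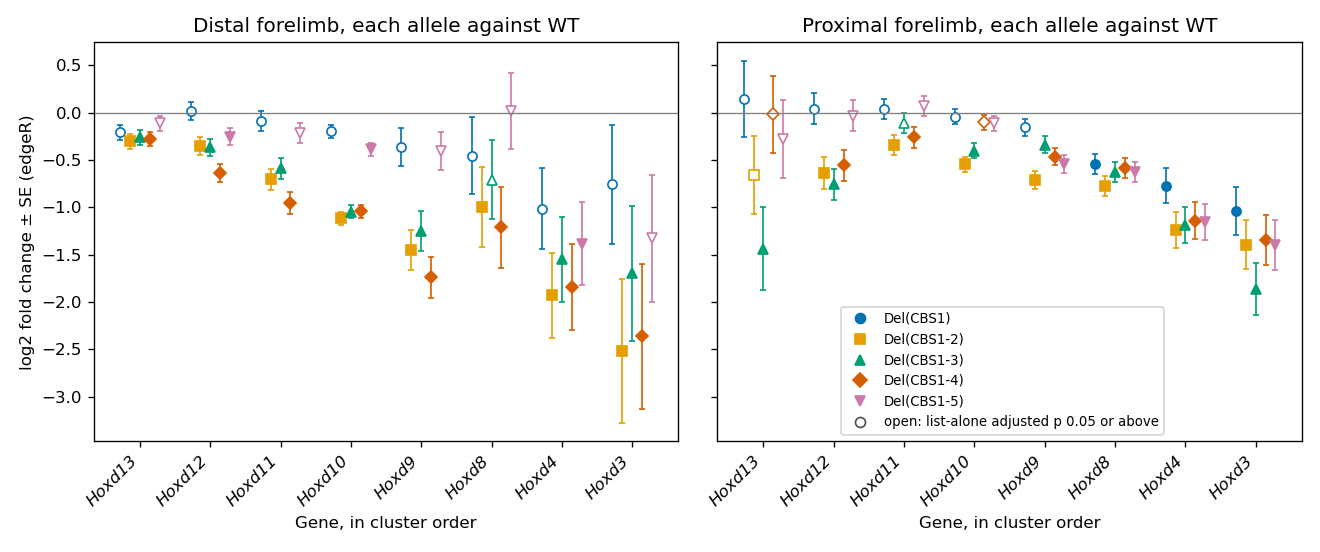
Log2 fold change against WT (y axis) of the 8 tested HoxD genes in cluster order (x axis) for 5 alleles, in distal and proximal tissue, with bars for the SE and filled symbols where the edgeR adjusted p over the list alone was under 0.05. Distal Hoxd10 sits at -0.20 in Del(CBS1), between -1.12 and -1.04 in the next 3 alleles and at -0.39 in Del(CBS1-5), and proximal Hoxd4 lies between -1.24 and -0.77 in all 5.

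The series was also read step by step, each allele against the preceding one. In distal tissue, Hoxd9 (-1.09 ± 0.21), Hoxd10 (-0.92 ± 0.07), Hoxd11 (-0.62 ± 0.11) and Hoxd12 (-0.37 ± 0.09) fell from Del(CBS1) to Del(CBS1-2), with 3 of 3 libraries below those of Del(CBS1) in each. Thus 4 of 8 genes passed, both over the list alone and over all genes. Hoxd13 (-0.09 ± 0.08), Hoxd8 (-0.54 ± 0.43), Hoxd4 (-0.92 ± 0.47) and Hoxd3 (-1.76 ± 0.82) did not pass. Between Del(CBS1-3) and Del(CBS1-2) edgeR called 0 HoxD genes on either count, with values from -0.02 (Hoxd12) to 0.82 (Hoxd3), 0 at an unadjusted p under 0.05, and 0 by DESeq2 and limma on FPKM. In Del(CBS1-4) against Del(CBS1-3), Hoxd11 (-0.37 ± 0.11; edgeR, Benjamini-Hochberg adjusted p over the list alone = 0.0383, 3 of 3 libraries lower) and Hoxd12 (-0.27 ± 0.09; 0.043, 1 of 3) fell, and Hoxd11 passed over all genes too. This count of 2 was 0 by limma on FPKM, with only the 6 libraries compared and with the boundary score as a covariate, and 0, 1 and 0 without Del(CBS1-3) 1, Del(CBS1-3) 3 and Del(CBS1-4) 3. The other 6 genes did not pass, with Hoxd9 (-0.49 ± 0.23) nearest.

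In the last step in distal tissue 5 HoxD genes rose. From Del(CBS1-4) to Del(CBS1-5), Hoxd9 rose from 7.24 ± 0.518 to 18.4 ± 1.54 CPM (1.33 ± 0.22), Hoxd10 from 54.1 ± 2.34 to 85.6 ± 5.13 (0.65 ± 0.07; edgeR, Benjamini-Hochberg adjusted p over the list alone = 2.35e-07), Hoxd11 by 0.74 ± 0.11, Hoxd12 by 0.38 ± 0.09 and Hoxd8 by 1.23 ± 0.43. In each of them 3 of 3 libraries lay above those of Del(CBS1-4). All but Hoxd8 passed over all genes. Hoxd13 (0.16 ± 0.08), Hoxd4 (0.46 ± 0.49) and Hoxd3 (1.03 ± 0.88) did not pass. Flanking genes moved in the steps as well. Nfe2l2 (0.25) rose in Del(CBS1-3) against Del(CBS1-2), and Atp5g3 (-0.22) and Chn1 (-0.18) fell in the next step. In the last one Atp5g3 (0.29 ± 0.06), Atf2 (0.21 ± 0.05), Chn1 (0.19 ± 0.05), Nfe2l2 (0.28 ± 0.07) and Ttc30a1 (0.44 ± 0.12) rose over all genes, 5 of 14. Adjusted over the list alone 7 were up and 1 down. Ttc30a1 can share reads with near-identical Ttc30 copies and is uncertain.

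In proximal tissue, the genes that fell from Del(CBS1) to Del(CBS1-2) were Hoxd9 (-0.56 ± 0.09), Hoxd10 (-0.51 ± 0.08; edgeR, Benjamini-Hochberg adjusted p over the list alone = 3.6e-05), Hoxd11 (-0.38 ± 0.11), Hoxd12 (-0.68 ± 0.17) and Hoxd4 (-0.47 ± 0.20), 5 over the list alone and 3 over all genes. All had 3 of 3 libraries below those of Del(CBS1). The count was 3 without Del(CBS1) 2. Hoxd3 (-0.36 ± 0.27), Hoxd8 (-0.23 ± 0.11) and Hoxd13 (-0.81 ± 0.42) did not pass. In Del(CBS1-3) against Del(CBS1-2) Hoxd9 rose by 0.37 ± 0.09 (edgeR, Benjamini-Hochberg adjusted p over the list alone = 0.00695, 3 of 3 libraries above), and the count of 1 became 0 without Del(CBS1-2) 3 or Del(CBS1-3) 3. In Del(CBS1-4) against Del(CBS1-3) Hoxd10 (0.30 ± 0.08; 0.0106, 3 of 3) and Hoxd13 (1.42 ± 0.44; 0.0187, 2 of 3) rose in edgeR with Benjamini-Hochberg adjustment over the list alone. Their count was 0 without Del(CBS1-3) 2 or Del(CBS1-4) 1, 1 without Del(CBS1-4) 2, and 1 by limma on FPKM or with the boundary score. Evx2 rose in this step as well and Atp5g3 fell (-0.25 ± 0.05), where Evx2 had 2, 1 and 1 counts in the proximal Del(CBS1-3) libraries. In Del(CBS1-5) against Del(CBS1-4) Hoxd11 (0.33 ± 0.11) and Hoxd12 (0.53 ± 0.17) rose with 3 of 3 libraries above (edgeR, Benjamini-Hochberg adjusted p over the list alone = 0.0305 for both, 0 over all genes). That count was 0 without Del(CBS1-4) 2, Del(CBS1-4) 3 or Del(CBS1-5) 2, 1 without Del(CBS1-5) 1 and 1 by limma on FPKM. Hnrnpa3 (0.28 ± 0.07) rose and Agps (-0.25 ± 0.07) fell in it over all genes. Each step compared different mutant lines, for which the labels name no litter or batch. The further deletion was thus not separated from other differences between the lines. The calls of the steps were not confined to the cluster. In their order edgeR called 380, 1003, 1645 and 2563 of 15361 genes in distal and 236, 1150, 2181 and 1627 of 15813 in proximal tissue, of which 376, 1002, 1642 and 2554, and 233, 1149, 2177 and 1625, lay outside HoxD and its flanks. Above 1.5-fold there were 125, 365, 536 and 845 in distal and 93, 329, 541 and 544 in proximal tissue. With the boundary score as a covariate the counts were 26, 46, 212 and 125 in distal and 146, 1127, 944 and 1625 in proximal tissue. Leaving out single libraries gave 39 to 202, 200 to 1439, 286 to 1901 and 701 to 3083 in distal and 11 to 622, 126 to 1680, 822 to 2140 and 110 to 2104 in proximal tissue.

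**Figure D2:**
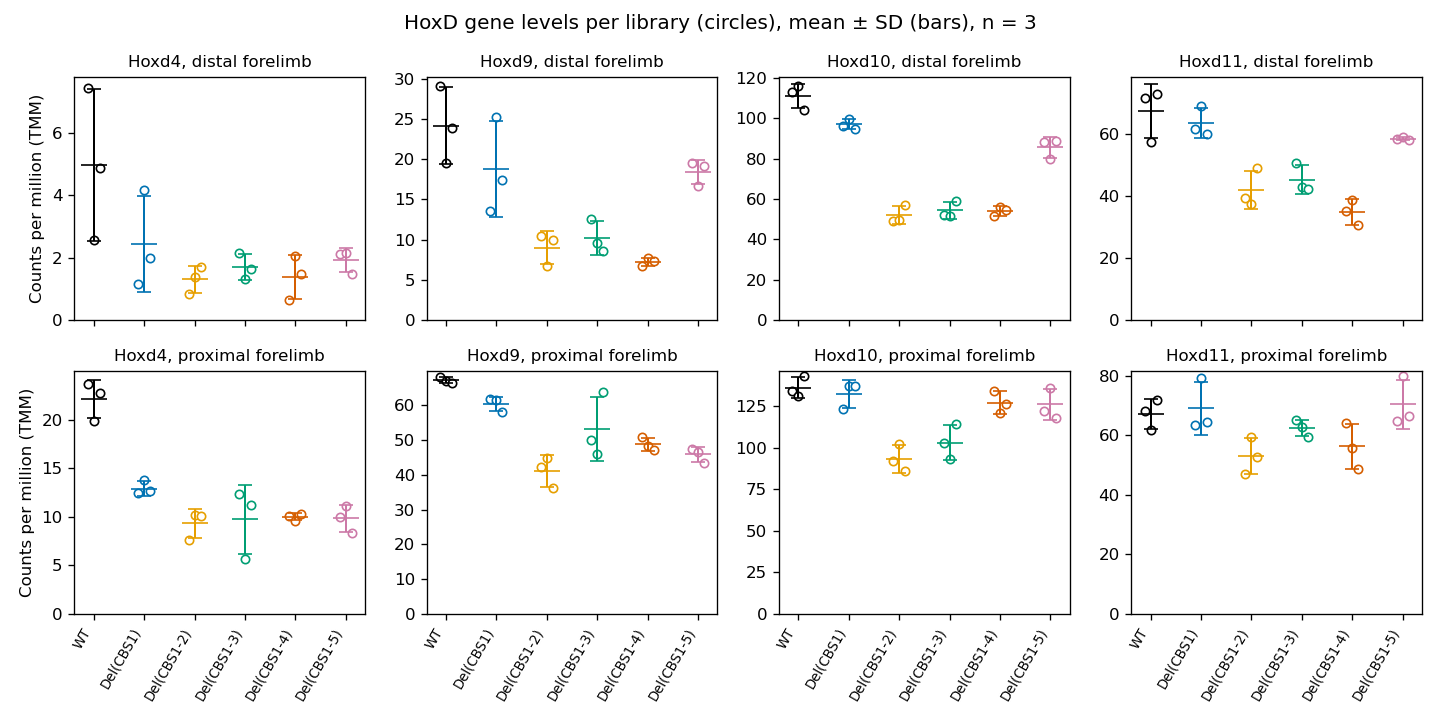
CPM (y axis) of Hoxd4, Hoxd9, Hoxd10 and Hoxd11 in each library (circles) of the 6 genotypes (x axis) in both tissues, with the mean and SD of 3 libraries. Distal Hoxd10 lies at means of 111, 97, 52, 54.3, 54.1 and 85.6 CPM from WT to Del(CBS1-5), and proximal Hoxd4 at 22.1 CPM in WT and 9.31 to 12.9 CPM in the mutants.

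Whether an allele acted differently in the tissues was tested as an interaction, given as the distal minus the proximal log2 fold change. In Del(CBS1-2), Hoxd10 (-0.55 ± 0.11; edgeR, Benjamini-Hochberg adjusted p over the list alone = 0.000141) and Hoxd9 (-0.72 ± 0.23; 0.0153) fell more in distal than in proximal tissue on the log2 scale. In both tissues all 3 mutant libraries lay below all WT libraries, so that separation does not bear on the difference. In CPM, Hoxd9 went from 24.2 to 9.01 in distal and from 67.2 to 41.1 in proximal tissue. In Del(CBS1-3), Hoxd9 (-0.90 ± 0.23), Hoxd10 (-0.63 ± 0.11) and Hoxd11 (-0.47 ± 0.17) fell more in distal tissue and Hoxd13 (1.19 ± 0.45) in proximal tissue. In Del(CBS1-4) Hoxd9 (-1.28 ± 0.24), Hoxd10 (-0.94 ± 0.11) and Hoxd11 (-0.70 ± 0.17) fell more in distal tissue. Over all genes the HoxD counts were 1, 1 and 2. The Hoxd13 value was 0.60 and did not pass without proximal WT 2, which had 1443 Hoxd13 counts against 490 and 498 in the other proximal WT libraries. With embryos blocked, Hoxd11 in Del(CBS1-2) (-0.34; edgeR, Benjamini-Hochberg adjusted p over the list alone = 0.0204) and Hoxd12 in Del(CBS1-3) (0.40; 0.0245) passed too, and Hoxd11 in Del(CBS1-4) passed over all genes (0.0273). For Del(CBS1) and Del(CBS1-5) edgeR called 0 HoxD genes, adjusted over the list alone and over all genes, and 0 by DESeq2 and limma on FPKM, but 1 and 5 over the list alone without a filter on low counts.

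Among 16292 genes, the interaction was called in 0 genes for Del(CBS1) (345 at an unadjusted p under 0.05), 8 for Del(CBS1-2), 1 for Del(CBS1-3), 3 for Del(CBS1-4) and 0 for Del(CBS1-5) (966 at an unadjusted p under 0.05). For the middle 3 alleles DESeq2 called 81, 1 and 12, limma on FPKM 0, 1 and 3, and leaving out single libraries gave 0 to 12, 0 to 1 and 1 to 12. With embryos blocked their counts were 116, 0 and 7, and Hoxd10 in Del(CBS1-3) had an adjusted p = 0.122 by edgeR with Benjamini-Hochberg adjustment (-0.63). Besides Hoxd10, Del(CBS1-2) differed in Smpd3 (-4.89 ± 0.87), Ccbe1 (-1.33 ± 0.22), a factor of lymphatic growth, and in the hyaluronan synthase gene Has2 (-0.83 ± 0.16) and Nsg2 (1.10 ± 0.19). It also differed in the retinoic acid binding protein gene Crabp2 (0.57 ± 0.10), the growth factor receptor gene Fgfr1 (0.32 ± 0.06) and Raly (0.32 ± 0.06). Del(CBS1-4) differed in Has2 (-0.91 ± 0.16). The HoxD interaction count was 1 without distal WT 1 or distal Del(CBS1-2) 2 in Del(CBS1-2), and 2 without distal WT 1, distal WT 3, proximal WT 2 or distal Del(CBS1-3) 3 in Del(CBS1-3).

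Of the remaining lists, other Hox clusters (lowest camera adjusted p = 0.0666, between WT tissues) and immediate early and heat shock genes (lowest 0.37) were called in no comparison with WT or between WT tissues by limma camera.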

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

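The tests of the 3 patterns below and the splits were chosen only after the results were seen, apart from the test of developmental progress, which was written down before it was run.

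A difference between the tissues brought up 9 HoxD values, given as distal minus proximal log2 fold change and tested as an interaction in edgeR without an embryo block. They were Hoxd9 (-0.72) and Hoxd10 (-0.55) in Del(CBS1-2), Hoxd9 (-0.90), Hoxd10 (-0.63), Hoxd11 (-0.47) and Hoxd13 (1.19) in Del(CBS1-3), and Hoxd9 (-1.28), Hoxd10 (-0.94) and Hoxd11 (-0.70) in Del(CBS1-4). Without proximal WT 2 the Hoxd13 value was 0.60 and did not pass. The same rule over all genes brought up Crabp2 (0.57), Nsg2 (1.10), Has2 (-0.83), Raly (0.32), Fgfr1 (0.32), Smpd3 (-4.89) and Ccbe1 (-1.33) in Del(CBS1-2) and Has2 (-0.91) in Del(CBS1-4). In Del(CBS1-2) the distal and proximal fold changes against WT were -2.12 and 2.79 for Smpd3, -0.92 and 0.43 for Ccbe1, -0.56 and 0.30 for Has2, 0.29 and -0.26 for Crabp2, 0.21 and -0.09 for Raly, 0.20 and -0.09 for Fgfr1 and 0.997 and -0.08 for Nsg2, and in Del(CBS1-4) they were -0.51 and 0.40 for Has2. All 7 genes passed over all genes in distal Del(CBS1-2) and Smpd3 alone in proximal Del(CBS1-2), while Has2 passed in neither tissue of Del(CBS1-4).

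Calls also appeared in genes that the comparisons do not use, those on chromosomes X and Y. These are in the deposited FPKM table alone and were tested by limma on log2(FPKM + 0.1). All genes called lay on chromosome X. In distal Del(CBS1-2) against WT 16 of 505 genes were called (101 at an unadjusted p under 0.05), among them Mcts1 (-0.23), Atp6ap1 (0.21), Maged1 (0.26), Chm (-0.33), Phf6 (-0.20), Xiap (-0.30), Gpc4 (0.46), Pqbp1 (0.26), Ints6l (-0.33), Upf3b (-0.41), Fam199x (-0.42), Gprasp1 (-0.18), Brwd3 (-0.39), Vma21 (-0.43) and Gm6368 (-4.69). All 3 Del(CBS1-2) embryos were female and 2 of 3 WT embryos, so the groups differ in sex for these genes. Maged1 (0.19) was called in distal Del(CBS1-4), and Acot9 (0.34), Gpc3 (0.19) and AA414768 (0.85) of 535 genes in proximal Del(CBS1-2) (80 at an unadjusted p under 0.05). Elsewhere limma called 0, with 26 to 69 genes at an unadjusted p under 0.05. By edgeR on counts, 4085 of 15361 autosomal genes in distal and 3084 of 15813 in proximal Del(CBS1-2) had an unadjusted p under 0.05. These are larger shares than those of the X and Y genes, which thus did not stand out, though the tests differ.

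The first pattern was that each WT embryo resembled 1 mutant line most: WT 1 deviated from the WT mean in the direction of Del(CBS1-3) (r = 0.52 distal, 0.50 proximal), WT 2 of Del(CBS1-4) (0.64, 0.58) and WT 3 of Del(CBS1-5) (0.41, 0.39), with lower values for WT 1 and Del(CBS1) (0.22, 0.24) and for WT 2 and Del(CBS1-2) (0.08, 0.19). For a haplotype on a few chromosomes, the correlation was above 0.1 in both tissues on at least 17 of 19 autosomes in every match. This shows where the deviating genes lie, and a variant may act on genes of other chromosomes, so it cannot decide. For the sex of the embryos, 3 of the 3 lines held an embryo of the other sex. This cannot decide, because every line but Del(CBS1-2) held both sexes. Other values argue against sex alone. Del(CBS1-4) and Del(CBS1-5) had the same sexes (female, male and female). Yet WT 3 had r = -0.35 distal and -0.2 proximal with Del(CBS1-4), against 0.41 and 0.39 with Del(CBS1-5). WT 1 and WT 2 were both female, yet WT 1 had r = -0.31 and -0.36 with Del(CBS1-4), against 0.64 and 0.58 for WT 2. Leaving out the matching WT library gave the highest count of changed genes in 6 of 6 comparisons (169 and 52 in Del(CBS1-3), 525 and 293 in Del(CBS1-4), 320 and 47 in Del(CBS1-5), distal and proximal), which restates the resemblance and does not bear on its cause. A shared litter, day or library batch stays possible and untested, since the labels name none. Apart from the haplotype and the sex, no biological explanation was tested.

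The second pattern was the near absence of processed copies such as Rps18-ps6 in Del(CBS1-2). Of 9 pairs of copy and parent, 7 had a copy with at least 5% of the pair's counts in WT, and the share went from 76% to 0.198% for Rps18-ps6, 51.5% to 0.545% for Hmga1b, 54.2% to 0.302% for Atp6v0c-ps2 and 24.5% to 0.306% for Pcna-ps2, while 5 of the 7 parents lie on chromosome 17. Lower transcription of the copies alone was argued against, as the parents' median change was 0.67 in distal tissue. Reads moving between copy and parent could account for part of the pairs, with a median change of the summed count of 0.03 in distal and -0.19 in proximal tissue, but the distal sums ran from -0.83 (Glo1) to 1.03 (Atp6v0c), and the parent Glo1 was lower (-0.73) along with its copy, which moving reads do not give. A strain variant against the reference stays open, and its bounds (embryos over 50 points apart, tissues of an embryo within 15 points) cannot decide it. They were met by 3 of 7 pairs, and the others could not meet them, as their copy never held over 44.7% of the counts. The share also differed among WT embryos, alike in both tissues. Rps18-ps6 held 96.5%, 64.3% and 67.2% in distal WT 1, 2 and 3, and 96.7%, 63.9% and 66.6% in proximal WT. Such differences within WT are not an effect of an allele.

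The third pattern was the higher level of HoxD genes in distal Del(CBS1-5) than in distal Del(CBS1-4). Proximal tissue in the distal samples was argued against for Hoxd8, Hoxd9 and Hoxd10, which were higher in proximal WT tissue, since the skeletal muscle list moved the other way (median -1.53). Hoxd12 was higher in distal WT tissue, so less proximal tissue in Del(CBS1-5) could raise it. For Hoxd12 the test thus cannot decide. Hoxd11 did not differ between the WT tissues. In Del(CBS1-4) it stood at 56.2 ± 7.68 CPM in proximal and 34.9 ± 4.13 CPM in distal tissue. Less proximal tissue would not raise such a gene, so its rise argues against the explanation for Hoxd11 as well. A difference in developmental progress may contribute and was left undecided: with the chondrogenesis level as a covariate 3 of the 5 HoxD genes still passed in edgeR (Hoxd10 0.62 ± 0.12, Hoxd9 1.35 ± 0.36, Hoxd11 0.49 ± 0.17), and Hoxd12 (0.09 ± 0.13) and Hoxd8 (0.63 ± 0.72) did not. The loss of the fifth site was not separated from other differences between the lines.

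Each comparison was repeated, without an embryo block, on the 10 splits of its 6 libraries into groups of 3 (for the tissue difference, of the embryos). The share of splits with as many calls therefore cannot go under 0.1. The splits between the WT tissues were made without regard to the pairing by embryo. For genes changed against WT, the count of the true groups and the highest of the other splits were, from Del(CBS1) to Del(CBS1-5), 5 and 0, 1606 and 0, 1 and 91, 13 and 2, 10 and 24 in distal tissue, and 7 and 0, 114 and 0, 11 and 60, 0 and 51, 11 and 5 in proximal tissue. At least as high were 1, 1, 4, 1 and 2 of 10 splits in distal and 1, 1, 2, 10 and 1 in proximal tissue. For HoxD genes they were 0 and 5, 8 and 3, 7 and 5, 8 and 3, 3 and 0 in distal and 3 and 1, 7 and 0, 7 and 0, 6 and 1, 4 and 0 in proximal tissue (10, 1, 1, 1, 1 and 1, 1, 1, 1, 1 of 10), and between the WT tissues 4578 and 0 for genes (1 of 10). The step counts of HoxD genes were 4 and 0, 0 and 0, 2 and 1, 5 and 0 in distal and 5 and 0, 1 and 3, 2 and 2, 2 and 1 in proximal tissue (1, 10, 1, 1 and 1, 2, 2, 1 of 10). For the tissue difference they were 0 and 3, 2 and 0, 4 and 0, 3 and 2, 0 and 0 for HoxD genes (10, 1, 1, 1, 10 of 10) and 0 and 1, 8 and 0, 1 and 1, 3 and 36, 0 and 0 for all genes (10, 1, 2, 2, 10 of 10). The splits with 91, 60, 51, 24 and 36 calls point to structure among the samples other than the genotype. Each of them grouped a WT embryo with embryos 1 and 2 of the line it resembled most in the first pattern. These were WT 1 with Del(CBS1-3) (91 and 60), WT 2 with Del(CBS1-4) (51 and 36) and WT 3 with Del(CBS1-5) (24). Other splits that grouped a WT embryo with its line in this way gave fewer calls.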

How the results depend on the processing

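The boundary score was an alternative chosen after seeing the data, and the other settings and their tests were planned. No result reversed. DESeq2 size factors in edgeR changed no call among 192 HoxD fold changes and 79 named genes. The named genes lost their call in 155 instances and kept it in 319 with leave-one-out, in 28 against 30 with only the 6 libraries compared, 26 against 33 with the boundary score, 25 against 54 by limma on FPKM, 14 against 65 with a replicate block and 1 against 78 with the DESeq2 Wald test. Among HoxD fold changes 185 kept their side of the threshold with a replicate block, 188 with the DESeq2 Wald test and 157 without a filter. The 11062069 to 17727891 counts of the libraries limit low genes such as Hoxd1. Without a filter the prior degrees of freedom went from 5.92 (distal) and 6.37 (proximal) to no finite value while the genes tested rose from 15361 to 30484 and from 15813 to 31247. For the other settings the cause was not tested, apart from the fewer libraries of leave-one-out and of the 6 libraries compared and the stricter bound of the 1.5-fold setting. The groups of 2 left by leave-one-out were fitted with the spread pooled over all groups. With a replicate block, the calls of HoxD, flanking and named genes among the paired results, and of lists between the WT tissues and in Del(CBS1-3), that changed are printed in the report. The counts changed there too, from 4578 to 5763 between the WT tissues and from 11 to 13 in proximal Del(CBS1-3).

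Genes changed against WT, from Del(CBS1) to Del(CBS1-5) in distal tissue, were 5, 1606, 1, 13 and 10. Without a filter they were 361, 551, 1073 and 633 (Del(CBS1), Del(CBS1-3), Del(CBS1-4), Del(CBS1-5)), and with the DESeq2 Wald test 65, 136, 295 and 119. With a replicate block Del(CBS1) had 1 and Del(CBS1-5) 6. With only the 6 libraries compared there were 3, 934, 2 and 3 (all but Del(CBS1-3)), by limma on FPKM 1, 869 and 4 (Del(CBS1), Del(CBS1-2), Del(CBS1-5)), with the boundary score 2, 196, 3, 8 and 3, and with 1.5-fold 3, 311 and 8 (Del(CBS1), Del(CBS1-2), Del(CBS1-4)). Leave-one-out gave 1 to 40, 607 to 1439, 1 to 169, 6 to 525 and 2 to 320.

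In proximal tissue the counts were 7, 114, 11, 0 and 11. They were 250, 1367, 462, 881 and 362 without a filter, 25, 520, 144, 97 and 32 with the DESeq2 Wald test, and 2, 627, 0, 1 and 7 with only the 6 libraries compared. Del(CBS1-2) had 64 with a replicate block. By limma on FPKM there were 40, 6 and 3 (Del(CBS1-2), Del(CBS1-3), Del(CBS1-5)), with the boundary score 0 in Del(CBS1-3), and with 1.5-fold 4, 40, 4 and 7 (all but Del(CBS1-4)). Leave-one-out gave 1 to 15, 30 to 291, 0 to 52, 0 to 293 and 2 to 47. Between WT tissues 4578 became 2088 with 1.5-fold, and 3526 to 4314 with leave-one-out.

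HoxD genes changed against WT were 0, 8, 7, 8 and 3 in distal tissue, with leave-one-out ranges 0 to 3, 7 to 8, 6 to 8, 6 to 8 and 1 to 6. Del(CBS1) had 4 without a filter and 2 with DESeq2, and Del(CBS1-5) 7 without a filter, 5 with only the 6 libraries and 1 by limma on FPKM. In proximal tissue 3, 7, 7, 6 and 4 had ranges 3 to 3, 7 to 7, 6 to 7, 5 to 6 and 4 to 4. Steps in distal tissue (4, 0, 2 and 5) had ranges 4 to 6, 0 to 0, 0 to 2 and 4 to 6. The first was 7 without a filter, and that of Del(CBS1-4) was 0 with a replicate block, with only the 6 libraries, by limma on FPKM and with the boundary score. In proximal tissue steps (5, 1, 2 and 2) ranged over 3 to 6, 0 to 1, 0 to 2 and 0 to 2. That of Del(CBS1-3) was 3 without a filter and with only the 6 libraries, that of Del(CBS1-4) was 1 by limma on FPKM and with the boundary score, and that of Del(CBS1-5) was 1 by limma on FPKM. The interaction counts of HoxD genes (0, 2, 4, 3 and 0) ranged over 0 to 0, 1 to 3, 2 to 5, 3 to 4 and 0 to 0, were 1, 6, 6 and 5 without a filter (all but Del(CBS1-3)), and Del(CBS1-3) had 2 by limma on FPKM.

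Gene counts of the steps were 380, 1003, 1645 and 2563 in distal tissue. They were 135, 688, 1264 and 2183 with a replicate block, 108, 515, 911 and 1699 by limma on FPKM and 26, 46, 212 and 125 with the boundary score, and leave-one-out gave 39 to 202, 200 to 1439, 286 to 1901 and 701 to 3083. Without a filter they were 1408, 1798, 2357 and 2902, with the DESeq2 Wald test 740, 1237, 1873 and 2628 and with only the 6 libraries compared 1234, 1074, 1170 and 2237. In proximal tissue 236, 1150, 2181 and 1627 became 107, 668, 1787 and 1275 with a replicate block, 41, 597, 1890 and 952 by limma on FPKM and 146, 1127, 944 and 1625 with the boundary score, and leave-one-out gave 11 to 622, 126 to 1680, 822 to 2140 and 110 to 2104. There they were 1467, 2012, 2667 and 2430 without a filter, 686, 1487, 2358 and 1943 with the DESeq2 Wald test and 1065, 1592, 1172 and 1453 with only the 6 libraries compared. Interaction counts over all genes (0, 8, 1, 3 and 0) were 29, 314, 111, 272 and 94 without a filter, 0, 81, 1, 12 and 0 with the DESeq2 Wald test and 0, 0, 1, 3 and 0 by limma on FPKM, and leave-one-out gave 0 to 0, 0 to 12, 0 to 1, 1 to 12 and 0 to 0.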

Other observations

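No hypothesis was tested in this part, and the comparisons, lists and tests used here were set before, except that Rbm44, Ihh, Gdf5 and Slc4a1 were chosen after their values were seen.

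Gene lists outside the cluster also moved between successive alleles in distal tissue. From Del(CBS1-4) to Del(CBS1-5), chondrogenesis (17 of 22 down), joint interzone (10 of 11), tendon and connective tissue (13 of 15), skeletal muscle (15 of 24) and Hedgehog pathway (10 of 11, with 1 up) were called lower, and erythroid cells (9 of 12 up, 1 down) and proliferation (9 of 16 up, 1 down) higher, in edgeR adjusted over each list alone. Over all genes 16, 10, 11, 6 and 9 were down, and 9 and 7 up. The limma camera calls had adjusted p = 0.144, 0.144, 0.144, 0.495, 0.117, 0.144 and 0.188 with an estimated correlation. Ihh stood at 4.01 ± 0.926, 4.07 ± 1.18, 10.5 ± 3.3, 3.35 ± 1.71, 10.3 ± 3.46 and 2.09 ± 1.43 CPM (SD, n = 3) from WT to Del(CBS1-5), Gdf5 of the joints at 98.7 ± 23.6, 97.7 ± 28.3, 181 ± 11.5, 91.3 ± 42.9, 172 ± 12.7 and 89 ± 23.7 CPM, and the red cell gene Slc4a1 at 75 ± 20.1, 66 ± 17.2, 48.9 ± 4.96, 71.1 ± 16.8, 34.9 ± 2.46 and 102 ± 36.4 CPM. In these genes Del(CBS1-2) and Del(CBS1-4) lay on one side of the other groups by their means.

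In proximal tissue, proliferation genes were called in every step by edgeR adjusted over the list alone: 12 of 16 down from Del(CBS1) to Del(CBS1-2), 15 up in the next step, 15 down in the one after and 14 up in the last. Over all genes 1, 10, 10 and 12 were called. The limma camera calls had adjusted p = 0.435, 0.425, 0.496 and 0.227 with an estimated correlation. Successive steps share a group of libraries, so their directions are not independent of each other.

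The summed CPM of the HoxD genes was 1650 ± 95.5 in distal WT and 1490 ± 48.1, 1280 ± 63.1, 1300 ± 122, 1210 ± 108 and 1480 ± 31.5 from Del(CBS1) to Del(CBS1-5) (SD, n = 3). In proximal tissue it was 462 ± 15.1 in WT and 436 ± 66.9, 301 ± 19.9, 317 ± 28.7, 371 ± 49.5 and 391 ± 27.9.

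Rbm44, which encodes an RNA-binding protein of germ cells (chromosome 1, 91145101 to 91170795), had 9 to 43 counts in the 6 Del(CBS1) libraries of both tissues and 0 to 1 in the other 30 libraries. It was among the calls in proximal tissue (edgeR, Benjamini-Hochberg adjusted p = 0.0354, with 1.86 ± 1.5 CPM in Del(CBS1) and 3 of 3 libraries above all WT libraries).

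By sex linked FPKM values the embryos numbered 1, 2 and 3 were female, female and male in WT, and male, male and female in Del(CBS1) and Del(CBS1-3). All 3 were female in Del(CBS1-2), and in Del(CBS1-4) and Del(CBS1-5) they were female, male and female.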
